A study of Mus musculus with 21 samples.

How the data were processed

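RNA was taken from livers of mice that lacked ERK1 throughout the body, ERK2 in hepatocytes, or both, 3 weeks after 3 mg of tamoxifen had been injected once under the skin, per the labels. ERK1 and ERK2 are the kinases at the end of the RAS-RAF-MEK cascade, and ERK1 is encoded by Mapk3. Tamoxifen acts here on a hepatocyte-expressed, tamoxifen-dependent Cre recombinase, which removes loxP-flanked sequence. The labels name both mRNA and total RNA, and the RNA selection step is not given in the sources used here. Per the labels, libraries were made with the NEBNext Ultra RNA kit and sequenced as 2 × 150 base paired-end reads on a NovaSeq 6000. The authors deposited 1 table of whole-number read counts per gene symbol for the 21 libraries, not normalised and with no row that names no gene. Per the submitters' processing notes the tools were FastQC, Trimmomatic, STAR, HTSeq, DESeq2 and edgeR and the builds mm10 and GRCm38; their versions, settings, gene annotation and the strand setting of the counting are not given in the sources used here. Every column of the table was matched to 1 sample by its title, and 0 columns were left unused.

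The genotype label of each sample gave 3 groups of 7 libraries: the ERK1 knockout (Erk1-null, floxed Erk2, no Cre), the ERK2 knockout (hepatocyte deletion of Erk2) and the double knockout (Erk1-null, floxed Erk2 and Cre). Replicate numbers follow the order of the samples and only name a library, so no library is paired with another. The labels do not tie libraries to separate animals beyond calling them separate samples, so p-values measure the spread between these samples, which may be partly technical. Mice without any knockout were not analysed here, so each comparison is between knockouts. Cre is present in the double knockout and the ERK2 knockout and absent from the ERK1 knockout, so a difference against the ERK1 knockout includes any effect of Cre.

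The table holds 24421 gene symbols. Total counts ran from 37703680 to 45460470 per library and 15875 to 16843 genes had at least 1 count, so depth differed little between libraries. The 10 most abundant genes took between 11.9% and 18.8% of the counts. Over the 63 pairs within groups, the lowest mean chi-square per gene, over genes with at least 100 counts, was 39.3. No 2 libraries of a group were thus duplicates, and pairs of libraries from different groups were not compared. Xist was near 0 and Y-linked genes were expressed in every library, so an adjustment for sex was not run.

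Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 14154, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 21 libraries. Each contrast was tested with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. A gene was called different in the double knockout from both single knockouts when its log2 fold changes had the same sign and the larger of its p-values, adjusted over all genes tested, was under 0.05. CPM values are counts scaled to a library's deposited total, and group values are means ± SD over libraries.

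Gene positions came from the RefSeq annotation of GRCm38.p6, in which 23204 of the symbols (95%) were found. The share of called genes within 10 Mb of Mapk3 was compared with that of other tested genes by a two-sided Fisher's exact test, leaving out both targeted genes.

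The 36 gene lists for pathways and cell types, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Of the lists, 34 had at least 5 tested members. Members of the mitochondrially encoded list were not tested, since 0 of its 13 symbols are in the table, and only 2 members of the erythroid list were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, then with an estimated correlation, and with fry. The number of members called was counted over all genes tested and, in addition, adjusted over the list alone. The named genes were the targeted genes, the 8 genes with the largest rise and the 8 with the largest fall per contrast among called genes with at least 5 CPM in the higher group, the 3 called members of each list with the largest change, and the same 8 and 8 for the comparison with both single knockouts by the smaller of the 2 changes. Where no list member was called, the member with the smallest p could be named. Results of 2 genes that the rule names are not reported here. Genes of other kinds are said to have been chosen after their values were seen.

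Comparisons that share the double-knockout libraries were set beside 20 simulated data sets in which no group differed, beside the overlap of independent lists, and beside the overlap after the double-knockout libraries were divided between the comparisons.

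The procedure was tested on 1 set of simulated counts drawn for the 14154 genes. In it 200 genes were changed in the double knockout. Besides them, 24 genes of the cholesterol list were raised there by 1 on the log2 scale. Every simulated library followed its label, whereas 5 of the real libraries were at odds with theirs. The shares called may therefore differ in the real fit. Of those of the 200 changed by 0.5, 1 or 2 on the log2 scale, 22.4%, 73.1% and 93.9% were called for the double against the ERK1 knockout, with 16 of the 24 list genes and 2 false calls among 144 calls in all. For the double against the ERK2 knockout the shares were 29.9%, 77.6% and 92.4%, with 18 list genes and 3 false calls among 154. For the double against both they were 19.4%, 71.6% and 92.4%, with 14 list genes and 0 false calls among 136, and the ERK2 against the ERK1 knockout, where nothing was changed, gave 0 calls.

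The alternatives were DESeq2 size factors within edgeR, library size without TMM factors, no filter on low counts, a filter of at least 1 CPM in 7 libraries, DESeq2 1.42.0, limma voom with sample quality weights, only the 2 groups compared in the fit, a required absolute log2 fold change over 1, an estimated correlation for the lists, distances of 5 and 20 Mb, and each library left out in turn. After the data were seen, 5 libraries were found in which the level of a targeted gene lay on the side of the widest gap in CPM opposite to their label, and every result was computed again without them. For each count of called genes, 100 splits of the same libraries into groups of the same sizes, the real one included, were also tested. Genes of multigene families, here Cyp2a, Cyp2b, Cyp3a, Cyp4a, Sult2a, Gsta, Gstm, Orm, Saa, Mup and H2-Q members, share sequence, so counts may be split unevenly among their members and single-member values are uncertain.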

Results

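Liver RNA was sequenced from mice lacking the kinase ERK1, the kinase ERK2, or both, with 7 libraries per knockout and 21 in all. ERK1 was missing throughout the body and ERK2 was removed from hepatocytes, the main cell type of the liver, by tamoxifen-activated Cre 3 weeks before sampling. Total counts ran from 37703680 to 45460470 per library. The double knockout was compared with each single knockout, to ask what the loss of the other kinase adds, and the single knockouts were compared with each other. The first principal component over the tested genes held 54.5% of the variance and the next 10.8%.

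Mapk3 was examined first, as a check of the labels. Mapk3, which encodes ERK1, lies on chromosome 7 (126759626 to 126765816, GRCm38). Counts are given per gene symbol, so reads from parts of the gene that were not deleted are included. Grouped by label, Mapk3 was at 13.8 ± 11.7 CPM in the ERK1 knockout, 28.3 ± 12.6 CPM in the ERK2 knockout and 11 ± 11.3 CPM in the double knockout (mean ± SD, n = 7 each).

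These large spreads came from 4 libraries whose Mapk3 level went against their labels. The library labelled ERK1 KO 2 had Mapk3 at 39.9 CPM. The library labelled double KO 7 had Mapk3 at 36.5 CPM. The libraries labelled ERK2 KO 5 and ERK2 KO 7 had Mapk3 at 9.45 and 10.9 CPM. With the library labelled ERK1 KO 1, which the check of the labels also set apart and whose Mapk3 level of 6.50 CPM did not go against its label, 5 libraries were at odds with their labels. In the other 16 libraries, called the matching libraries from here on, Mapk3 was at 9.998 ± 1.42 CPM in the ERK1 knockout (n = 5), 35.6 ± 2.77 CPM in the ERK2 knockout (n = 5) and 6.78 ± 1.12 CPM in the double knockout (n = 6).

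With all 21 libraries as labelled, Mapk3 was lower by 1.48 ± 0.52 on the log2 scale in the double than in the ERK2 knockout (adjusted p = 0.0252). The single knockouts did not differ by the test in Mapk3 (log2 fold change 1.08 ± 0.51, adjusted p = 0.505), while in the matching libraries this value was 1.91 (adjusted p = 1.05e-06). Matching libraries were chosen in part by their Mapk3 level, so tests of Mapk3 within them follow from that choice and do not check the labels. The Mapk3 value against the ERK2 knockout was −2.27 without the library labelled double KO 7. Its call was lost without the library labelled double KO 2 (−1.35, adjusted p = 0.0501), double KO 4 (−1.40, 0.0506) or double KO 6 (−1.38, 0.0505). Against the ERK1 knockout, Mapk3 in the double knockout was at −0.40 ± 0.51 (adjusted p = 0.583). It was at −1.17 without the library labelled double KO 7 (adjusted p = 0.0298), at 0.20 without the library labelled ERK1 KO 2 and at −0.68 in the matching libraries (adjusted p = 0.000282). Group names are those of the labels throughout, and every direction rests on labels with which 5 libraries are at odds.

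**Figure D1:**
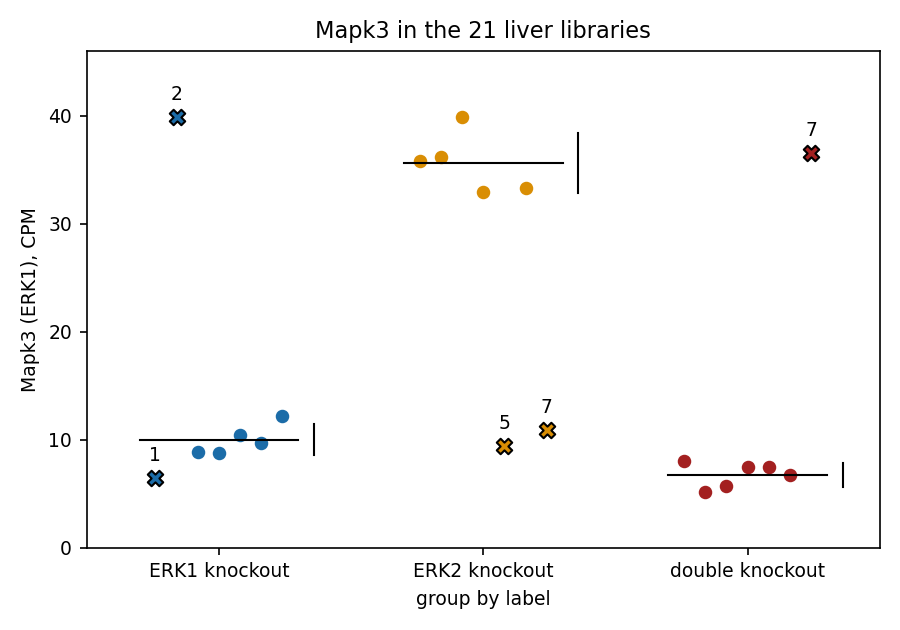
Mapk3 in CPM (vertical axis) for each of the 21 libraries by labelled knockout; points are matching libraries, numbered crosses the 5 libraries at odds with their labels by replicate, horizontal lines the mean of the matching libraries and vertical lines 1 SD on either side. The library labelled double KO 7 lies at 36.5 CPM, within the range of the matching ERK2 knockout libraries.

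The double knockout was set against the ERK1 knockout to ask what hepatocyte loss of ERK2 adds where ERK1 is already missing. Gstm3, a glutathione transferase (chromosome 3, 107963696 to 107969174), was higher in the double knockout, at 2680 ± 2280 CPM against 166 ± 314 CPM, a log2 fold change of 3.95 ± 0.81 (n = 7 each, adjusted p = 0.00563). Without the library labelled ERK1 KO 1, in which Gstm3 was at 876 CPM, it was higher by 5.68, and in the matching libraries the ERK1 knockout was at 50.8 ± 18.5 CPM (n = 5). Gpx2, a glutathione peroxidase (chromosome 12, 76792335 to 76795554), was higher by 5.18 ± 1.19 (adjusted p = 0.00779), or by 9.37 without the library labelled ERK1 KO 1, in which it was at 6.48 CPM. Alb, which encodes serum albumin (chromosome 5, 90460870 to 90476602), was at 9550 ± 9610 CPM against 56700 ± 28000 CPM, lower by 2.62 ± 0.55 (adjusted p = 0.00572). Without the library labelled double KO 7, in which Alb was at 31200 CPM, it was lower by 3.39, and in the matching libraries the double knockout was at 5942 ± 1250 CPM (n = 6). Collagen Col1a1 and the monocyte attractant Ccl2 were higher, and the cytochrome P450 gene Cyp2b9 fell from 270 ± 165 to 2.84 ± 2.09 CPM (log2 fold change −6.71 ± 1.14, adjusted p = 0.00474).

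Of 14154 tested genes, 1727 were higher and 1675 lower in the double than in the ERK1 knockout (3402 in all). In the matching libraries, chosen after the data were seen, 3271 were higher and 3280 lower (6551 in all), and 3372 of the 3402 were called there too, all with the same sign. Scaled by library size alone, the split was 2731 higher and 1104 lower, with the median of all genes shifted by 0.10 on the log2 scale. The count was 5146 without the library labelled ERK1 KO 1, 2211 without ERK1 KO 4, 2094 without double KO 4, 2268 without double KO 6 and 5609 without double KO 7. Presence of Cre is part of this contrast and cannot be separated from the loss of ERK2. Of 99 called genes named by rule besides Mapk3, 34 had a fold change that moved by over 1.5 times on the linear scale without 1 library, 15 of them without ERK1 KO 1 and 13 without double KO 7. None of the genes named changed sign under another scaling of the libraries.

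The largest rises, with Gpx2 and Gstm3, were in Chil3, a chitinase-like macrophage product (4.73 ± 1.13), Amn (4.32 ± 0.93), Gpnmb, expressed by lipid-laden macrophages (4.21 ± 1.32, adjusted p = 0.0277), the sulfotransferases Sult2a5 (4.17 ± 1.0) and Sult2a1 (3.97 ± 1.21), and F13a1 (3.84 ± 0.78). Gpnmb was higher by 8.76 without the library labelled ERK1 KO 1, and its call was lost without the library labelled ERK1 KO 4 (adjusted p = 0.0554), double KO 4 (3.44, adjusted p = 0.075) or double KO 5 (0.0522). Without the library labelled ERK1 KO 1, Amn was higher by 5.87, Sult2a1 by 4.83 and F13a1 by 4.48. Chil3 was higher by 5.59 without ERK1 KO 2 and by 3.49 without double KO 5, and Sult2a5 by 5.26 without ERK1 KO 6. Fitting only the compared groups ended that of Gpnmb (0.083) and that of Sult2a1 (0.0711). The largest falls, with Cyp2b9 (chromosome 7, 26173350 to 26210661), were in Cyp3a41a (−10.1 ± 2.13), Cyp3a44 (−9.44 ± 1.5), Sult3a1 (−8.39 ± 1.57), Cyp2b13 (−6.55 ± 1.32), the oxytocin receptor Oxtr (−6.50 ± 1.47), Rgs16 (−5.66 ± 1.36) and Cyp2a4 (−5.08 ± 1.07). Without the library labelled double KO 2, Cyp3a41a was at −11.3, Sult3a1 at −9.68 and Oxtr at −7.85. Without ERK1 KO 2, Cyp3a41a was at −9.42 and Rgs16 at −4.76, while Rgs16 was at −6.30 without double KO 7 and Cyp3a44 at −8.73 without ERK1 KO 6. With voom and sample weights the calls of Cyp3a41a (adjusted p = 0.182), Cyp3a44 (0.0692), Sult3a1 (0.198), Cyp2b13 (0.212), Oxtr (0.125), Rgs16 (0.336) and Cyp2a4 (0.0876) were lost.

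Among targets of NRF2, the transcription factor of the oxidative stress response, and glutathione genes, 13 of 17 rose against the ERK1 knockout, 0 fell and 4 did not pass (14 and 1 adjusted over the list alone). Besides Gstm3, Gsta1 rose by 3.06 ± 0.63 (adjusted p = 0.00563). The list was called upward by camera (median log2 fold change 1.39, adjusted p = 2.98e-07 and adjusted p = 0.474 with an estimated correlation). In the matching libraries 13 rose and 2 fell. Nuclear genes of the mitochondrial respiratory chain also moved upward, by little each: 19 of 23 rose, 0 fell and 4 did not pass (21 and 0 adjusted over the list alone; 20 rose in the matching libraries). Ndufs1 of complex I was higher by 0.47 ± 0.10, Ndufa4 by 0.44 ± 0.10 and Atp5b of the ATP synthase by 0.41 ± 0.10 (adjusted p = 0.00593, 0.0068 and 0.0106). Camera called this list too (median 0.28, adjusted p = 3.62e-10 and adjusted p = 0.621 with an estimated correlation).

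Of 14 fibrosis and myofibroblast genes, 11 rose, 0 fell and 3 did not pass against the ERK1 knockout (14 and 0 adjusted over the list alone; median 1.17, camera adjusted p = 2.98e-07 and adjusted p = 0.621 with an estimated correlation), and 13 rose in the matching libraries. Col1a1 (chromosome 11, 94936224 to 94953042) was at 56.2 ± 23.7 against 15.3 ± 12.6 CPM (1.78 ± 0.41, adjusted p = 0.0078). Timp1, an inhibitor of matrix proteases (chromosome X, 20870166 to 20874737), rose by 2.91 ± 0.73 (adjusted p = 0.0108), or by 4.60 without the library labelled ERK1 KO 1. Of 10 stellate cell markers, which also mark pericytes, 2 rose and 8 did not pass (3 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 0.0305 and adjusted p = 0.715 with an estimated correlation). Rgs5 rose by 1.03 ± 0.28 (adjusted p = 0.0148), and 6 of the markers rose in the matching libraries. Of 15 Kupffer cell and macrophage markers, 3 rose and 12 did not pass (2 and 0 adjusted over the list alone; median 0.72, and 1.21 in the matching libraries, camera adjusted p = 0.0305 and adjusted p = 0.715 with an estimated correlation), while 10 rose in the matching libraries. Trem2 (2.58 ± 0.82, adjusted p = 0.0303) and Cd68 (1.26 ± 0.45, adjusted p = 0.0471) were among the 3. Trem2 was higher by 4.36 without the library labelled ERK1 KO 1. Its call was lost without any 1 of 8 libraries, the libraries labelled ERK1 KO 2 to ERK1 KO 7, double KO 4 and double KO 5 (adjusted p from 0.0549 to 0.0692), and with only the compared groups fitted (0.0821). That of Cd68 was lost without any 1 of 17 libraries (adjusted p from 0.0509 to 0.126), with the lowest fold change, 0.95, without the library labelled double KO 5.

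Of 17 cytokines and chemokines, 9 rose, 0 fell and 8 did not pass (10 and 0 adjusted over the list alone; median 1.11, and 1.84 in the matching libraries, camera adjusted p = 0.0105 and adjusted p = 0.715 with an estimated correlation). There were 11 that rose and 1 that fell in the matching libraries. Ccl2 was at 12.2 ± 11.4 against 1.19 ± 1.42 CPM, higher by 3.26 ± 0.66 (adjusted p = 0.00563), and Ccl3 was higher by 3.32 ± 0.82 (adjusted p = 0.0101). Without the library labelled ERK1 KO 1 these values were 4.07 and 3.98, and that of Ccl3 was 2.53 without double KO 5. Sinusoidal endothelial markers moved the other way. Of 16, 1 rose, 9 fell and 6 did not pass (1 and 9 adjusted over the list alone and also in the matching libraries; median −0.41, camera adjusted p = 0.0184 and adjusted p = 0.715 with an estimated correlation). The VEGF receptors Kdr and Flt4 fell by 0.83 ± 0.20 and 0.69 ± 0.20 (adjusted p = 0.00872 and 0.0186). The endothelial list was not called in the matching libraries (adjusted p = 0.147).

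Hepatocyte identity genes, the liver transcription factors and secreted products, had 6 of 15 fall, 0 rise and 9 not pass (0 and 6 adjusted over the list alone; median −0.45, camera adjusted p = 0.00335 and adjusted p = 0.621 with an estimated correlation). Counts in the matching libraries were 1 that rose and 9 that fell. Of 12 growth hormone and STAT5 targets, 2 fell and 10 did not pass (0 and 3 adjusted over the list alone; median −0.54, and −1.17 in the matching libraries, camera adjusted p = 0.00335 and adjusted p = 0.621 with an estimated correlation), against 8 that fell in the matching libraries. Stat5a and Stat5b, which carry the growth hormone signal, fell by 1.30 ± 0.27 and 0.48 ± 0.13 (adjusted p = 0.00593 and 0.0148). Of 20 genes of the endoplasmic reticulum and amino acid stress response, 11 fell, 1 rose and 8 did not pass (1 and 12 adjusted over the list alone; median −0.57, camera adjusted p = 0.0123 and adjusted p = 0.715 with an estimated correlation; 1 rose and 12 fell in the matching libraries). The one that rose was the stress factor Atf3 (2.22 ± 0.43, adjusted p = 0.00506, and 2.97 without the library labelled ERK1 KO 1), while the AKT inhibitor Trib3 fell by 1.67 ± 0.42 (adjusted p = 0.0106; 0.0761 with voom). Of 25 cell cycle genes, 2 rose, 1 fell and 22 did not pass (0 and 1 adjusted over the list alone; median 0.87, camera adjusted p = 0.00257 and adjusted p = 0.715 with an estimated correlation). The replication gene Tk1 fell by 0.998 ± 0.28 (adjusted p = 0.0176, and 0.0614 with only the compared groups fitted). Of these, 3 rose and 1 fell in the matching libraries, and the list was not called there (adjusted p = 0.0555).

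In all, camera called 11 of the 34 lists against the ERK1 knockout, 7 upward and 4 downward, and 10 in the matching libraries. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05 (4 in the matching libraries), and fry called 7 (19 in the matching libraries). Of 23 ERK feedback and immediate-early targets, 2 rose and 3 fell (2 and 3 adjusted over the list alone, median 0.11, and 0.15 in the matching libraries). In the matching libraries scaled by library size alone, 6 rose and 6 fell. With all libraries Myc rose by 1.37 ± 0.32, and the feedback inhibitor Spry4 fell by 1.72 ± 0.43 (adjusted p = 0.00784 and 0.0108). Spred2 was at −1.4, and at −2.05 without the library labelled double KO 7. Dusp6, named here after its values were seen, was at 7.03 to 22.3 CPM in the matching double knockout libraries. It was at 22.1 to 57.1 CPM in the matching ERK1 knockout libraries. Members moved both ways, so the list median alone does not show that ERK targets were unchanged. Of 22 MAPK pathway components, 4 rose and 1 fell (6 and 3 adjusted over the list alone; median 0.077), with Hras higher by 0.37 ± 0.08. Of 14 bile acid synthesis genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, median 0.12). Cyp7a1, named here after its values were seen, was not among those called. It was at 634 to 900 CPM in the matching double knockout libraries and at 47.3 to 77.8 CPM in the matching ERK1 knockout libraries. The library labelled ERK1 KO 1 was at 1390 CPM and that labelled double KO 7 at 130 CPM. Of 18 genes of bile acid transport and its regulators, 3 rose and 7 fell (3 and 8 adjusted over the list alone; median −0.26). There the basolateral exporter subunit Slc51b rose by 2.89 ± 0.71 (4.21 without the library labelled ERK1 KO 1), while the sterol exporter Abcg8 fell by 2.22 ± 0.51 (−3.01 without double KO 7) and the nuclear receptor Nr0b2 by 3.11 ± 0.86 (adjusted p = 0.0161, and 0.0606 with only the compared groups fitted), or by 5.54 without the library labelled double KO 7.

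Lipid and sugar metabolism showed no shared direction against the ERK1 knockout. Of 21 fatty acid and triglyceride synthesis genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone; median 0.091), with the desaturase Scd2 higher by 1.35 ± 0.28. Of 31 fatty acid oxidation and PPAR-alpha targets, 6 rose and 8 fell (6 and 12 adjusted over the list alone; median −0.12), with Cyp4a31 lower by 2.44 ± 0.50. Of 24 cholesterol synthesis and uptake genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone; median −0.015). Of 14 lipoprotein genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; median −0.056), and of 20 glucose and glycogen genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone; median −0.036). The insulin receptor substrate Irs2 fell by 1.39 ± 0.35 (adjusted p = 0.0105). Of 21 pericentral genes, 1 rose and 5 fell (1 and 7 adjusted over the list alone; median −0.16), with the ethanol-oxidising Cyp2e1 lower by 1.15 ± 0.30 (adjusted p = 0.0132, and 0.0536 with only the compared groups fitted). Of 16 periportal genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone; median −0.34), with Aldh1b1 higher by 1.96 ± 0.39. Of 19 xenobiotic metabolism genes, 7 rose and 6 fell (9 and 6 adjusted over the list alone; median 0.34). Medians of the cholesterol, lipoprotein, glucose and lymphocyte lists changed sign under another scaling of the libraries. In the matching libraries the medians of the fatty acid synthesis, cholesterol, interferon and lymphocyte lists had the other sign, at −0.0734, 0.15, −0.0275 and 0.294.

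Among the remaining lists, 3 p53 targets rose and 1 of 15 fell (3 and 1 adjusted over the list alone; median 0.20), with the stress hormone Gdf15 lower by 3.28 ± 0.64 (adjusted p = 0.00563). Of 23 autophagy and lysosome genes, 4 rose and 3 fell (5 and 5 adjusted over the list alone, median 0.086), with the protease Ctsd higher by 0.94 ± 0.23. Scaled by library size alone, 8 of them rose and 1 fell. Of 26 acute phase genes, 1 rose and 9 fell (2 and 11 adjusted over the list alone; median −0.52, and 0.047 in the matching libraries), with Crp lower by 1.58 ± 0.35. Of 23 interferon response genes, 0 rose and 2 fell (0 and 0 adjusted over the list alone; median 0.014). Of 19 clock genes, 0 rose and 3 fell (0 and 1 adjusted over the list alone; median −0.26). Of 20 female-biased genes, 2 rose and 11 fell (3 and 11 adjusted over the list alone; median −1.65, camera adjusted p = 0.0596). Of 15 male-biased genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone; median 0.13), while 7 fell, 1 rose and the list was called downward in the matching libraries (median −1.83, adjusted p = 0.0256 and adjusted p = 0.862 with an estimated correlation). Of 7 fetal liver genes, 1 rose and 2 fell (2 and 3 adjusted over the list alone; median −0.91), with Afp, the fetal counterpart of albumin, lower by 0.98 ± 0.22. Among markers of other cells, 2 of 9 cholangiocyte genes rose and 1 fell (2 and 1 adjusted over the list alone; median 0.33), with Spp1 higher by 2.15 ± 0.48. In the same comparison 1 of 13 lymphocyte genes rose (1 adjusted over the list alone; median −0.019), 1 of 8 neutrophil genes rose (1 adjusted over the list alone; median 0.55, and 1.44 in the matching libraries) and 0 of 2 erythroid genes did (median 1.06). Median, mean and test differed in sign for the ERK target, MAPK, bile acid synthesis, fatty acid synthesis, lipoprotein, xenobiotic, interferon and male-biased lists.

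The double knockout was set against the ERK2 knockout to ask what the loss of ERK1 adds where hepatocytes already lack ERK2. Both groups carry Cre. Mice with and without the Erk1-null allele may also differ elsewhere in the genome, which was not separated from the loss of ERK1. The sulfotransferase Sult2a1 (chromosome 7, 13796246 to 13837410) was at 526 ± 250 CPM in the double and 0.315 ± 0.40 CPM in the ERK2 knockout, a log2 fold change of 10.5 ± 1.67 (n = 7 each, adjusted p = 0.000441). Gstm3 was at 2680 ± 2280 against 62.7 ± 14.9 CPM (5.21 ± 0.87, adjusted p = 0.000473). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275632), was at 696 ± 263 against 63.1 ± 59.5 CPM (3.27 ± 0.84, adjusted p = 0.0045). Col1a1 was at 56.2 ± 23.7 against 6.90 ± 2.92 CPM (2.84 ± 0.43, adjusted p = 0.000441). Alb was at 9550 ± 9610 against 50200 ± 18000 CPM, lower by 2.51 ± 0.54 (adjusted p = 0.00151), or by 3.29 without the library labelled double KO 7. Sult2a1 was higher by 11.3 without the library labelled ERK2 KO 2.

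In this comparison 3440 genes were higher and 2872 lower in the double knockout (6312 in all). In the matching libraries 3723 were higher and 3581 lower (7304 in all), and 6015 genes were called both times. Of 110 called genes named by rule besides Mapk3, 34 had a fold change that moved by over 1.5 times on the linear scale without 1 library, 14 of them without double KO 7. Scaled by library size alone the split was 5234 higher and 1513 lower, with the median of all genes shifted by 0.18 on the log2 scale.

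Among the largest rises after Sult2a1 were those of Gpx2 (9.56 ± 1.64), Sult2a2 (8.79 ± 1.49), Gpnmb (8.65 ± 1.76, at 64.8 ± 90.4 against 0.136 ± 0.096 CPM), Sult2a5 (8.45 ± 1.33), the macrophage elastase Mmp12 (8.33 ± 1.58) and H2-Q1 (7.62 ± 1.34). Without the library labelled ERK2 KO 2, Sult2a2 was higher by 9.49 and Sult2a5 by 9.79, and without double KO 4 Gpnmb was higher by 7.87 and Mmp12 by 7.37. The largest falls were in Sult3a1 (−7.66), Cyp3a44 (−7.47), Cyp3a41a (−7.22), Cyp2b9 (−6.74 ± 1.14, adjusted p = 0.000507), Cyp2b13 (−5.68 ± 1.28), Rgs16 (−5.61), Cyp2a4 (−4.92 ± 1.06) and the imprinted RNA Meg3 (−4.69 ± 0.64). Leaving out the library labelled ERK2 KO 2 gave −5.12 for Cyp3a41a, −4.88 for Rgs16 and −4.06 for Cyp2a4, and leaving out double KO 2 gave −8.43 for Cyp3a41a and −8.96 for Sult3a1. Rgs16 was at −6.28 without double KO 7 and Cyp3a44 at −6.14 without ERK2 KO 7. With voom the calls of Sult3a1 (adjusted p = 0.323), Cyp3a44 (0.202), Cyp3a41a (0.412), Cyp2b13 (0.247), Rgs16 (0.112) and Cyp2a4 (0.124) were lost.

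Of the 17 NRF2 and glutathione genes, 13 rose, 1 fell and 3 did not pass against the ERK2 knockout (13 and 2 adjusted over the list alone; median 1.57, camera adjusted p = 0.00014 and adjusted p = 0.582 with an estimated correlation). In the matching libraries 13 rose and 3 fell. Hmox1, which degrades haem, was at 185 ± 133 against 14.2 ± 4.73 CPM (3.53 ± 0.62, adjusted p = 0.00055). The cystine transporter Slc7a11 had 0 counts in all 7 ERK2 knockout libraries and was at least 16.4-fold higher in the double knockout, against a floor of 3 counts in a library. The list median was the same with Slc7a11 at that bound. Of the 23 respiratory chain genes, 13 rose and 10 did not pass (13 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 0.00114 and adjusted p = 0.656 with an estimated correlation), against 9 that rose and 1 that fell in the matching libraries. Scaled by library size alone, 21 of the respiratory chain genes rose and 0 fell, with all libraries and with the matching ones. Ndufa4 rose by 0.38 ± 0.10 (adjusted p = 0.00471) and Cox5a by 0.35 ± 0.08 (adjusted p = 0.00223).

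All 14 fibrosis and myofibroblast genes rose against the ERK2 knockout, over all genes, adjusted over the list alone and in the matching libraries (median 1.85, camera adjusted p = 1.1e-07 and adjusted p = 0.582 with an estimated correlation), with Timp1 higher by 5.06 ± 0.87 (adjusted p = 0.000517). Of 10 stellate cell markers, 8 rose and 2 did not pass (9 and 0 adjusted over the list alone; median 0.69, camera adjusted p = 0.00279 and adjusted p = 0.631 with an estimated correlation), and 10 rose in the matching libraries. The growth factor Hgf rose by 1.25 ± 0.28 and the proteoglycan Dcn by 1.07 ± 0.24 (adjusted p = 0.0021 for each). All 15 macrophage markers rose, also adjusted over the list alone and in the matching libraries (median 1.61, camera adjusted p = 0.000202 and adjusted p = 0.631 with an estimated correlation). Trem2 was higher by 4.82 ± 0.94 (adjusted p = 0.000852) and the scavenger receptor Marco by 3.31 ± 0.80 (adjusted p = 0.00314, and 4.27 without the library labelled ERK2 KO 3). Of 8 neutrophil markers, 7 rose and 1 did not pass (7 and 0 adjusted over the list alone; 7 in the matching libraries; median 2.18, camera adjusted p = 0.0119 and adjusted p = 0.631 with an estimated correlation). The granule protease Mmp8 rose by 4.13 ± 0.81 (4.74 without ERK2 KO 3) and S100a9 by 2.53 ± 0.62 (adjusted p = 0.000897 and 0.00327). Of 17 cytokines and chemokines, 12 rose and 5 did not pass (12 and 0 adjusted over the list alone; 12 in the matching libraries; median 1.62, camera adjusted p = 0.0024 and adjusted p = 0.631 with an estimated correlation), among them Ccl2 (4.12 ± 0.70) and the neutrophil attractant Cxcl2 (4.04 ± 0.73). The 16 sinusoidal endothelial markers had 1 that rose and 5 that fell (1 and 5 adjusted over the list alone; median −0.27, and −0.093 in the matching libraries, where library-size scaling turned it to 0.11); Kdr fell by 0.79 ± 0.20.

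Cell cycle genes rose with the macrophage and matrix genes. Of 25, 20 rose, 1 fell and 4 did not pass (20 and 1 adjusted over the list alone; median 1.46, camera adjusted p = 0.00054 and adjusted p = 0.656 with an estimated correlation). There were 18 that rose and 1 that fell in the matching libraries. Top2a, the topoisomerase of dividing cells, was at 11 ± 13.8 against 1.60 ± 1.5 CPM (2.58 ± 0.71, adjusted p = 0.00706, and 1.70 without the library labelled double KO 3). The mitotic kinases Bub1 and Aurkb were higher by 2.71 ± 0.76 and 2.64 ± 0.69. Without that library these were 1.89 and 1.80, and Bub1 was higher by 3.48 without the library labelled ERK2 KO 3.

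Of 15 hepatocyte identity genes, 9 fell and 6 did not pass against the ERK2 knockout (1 and 9 adjusted over the list alone; median −0.56, camera adjusted p = 0.00214 and adjusted p = 0.582 with an estimated correlation; 1 rose and 10 fell in the matching libraries), with the fibrinogen chain Fgb lower by 1.15 ± 0.23. Of 12 growth hormone and STAT5 targets, 4 fell and 8 did not pass (0 and 4 adjusted over the list alone; median −0.71, camera adjusted p = 0.00279 and adjusted p = 0.582 with an estimated correlation; 8 fell in the matching libraries). The growth hormone receptor Ghr fell by 0.62 ± 0.14 (adjusted p = 0.00234). Of 15 male-biased genes, 1 fell and 14 did not pass (0 and 1 adjusted over the list alone; median −0.73, and −2.70 in the matching libraries, camera adjusted p = 0.00636 and adjusted p = 0.656 with an estimated correlation), against 1 that rose and 10 that fell in the matching libraries. Of 18 genes of bile acid transport and its regulators, 3 rose, 10 fell and 5 did not pass (3 and 10 adjusted over the list alone; median −0.45, camera adjusted p = 0.013 and adjusted p = 0.582 with an estimated correlation; 3 and 11 in the matching libraries). Slc51b rose by 4.35 ± 0.78, and Nr0b2, which represses Cyp7a1, was at 4.83 ± 10.2 against 50.6 ± 13.1 CPM (−3.46 ± 0.87, adjusted p = 0.00394, and −5.91 without the library labelled double KO 7). Of 20 endoplasmic reticulum and amino acid stress genes, 1 rose, 11 fell and 8 did not pass (1 and 11 adjusted over the list alone; median −0.71, camera adjusted p = 0.00547 and adjusted p = 0.631 with an estimated correlation; 2 and 12 in the matching libraries). Atf3 rose by 3.04 ± 0.44 and Sesn2 fell by 1.51 ± 0.26.

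Camera called 13 of 34 lists against the ERK2 knockout, 8 upward and 5 downward, and 14 in the matching libraries. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05 (5 in the matching libraries), and fry called 17 (18 in the matching libraries). Among lists not called, 6 of 23 ERK feedback and immediate-early targets rose and 6 fell (6 and 7 adjusted over the list alone; median 0.38): Myc rose by 2.17 ± 0.33, while Spry4 fell by 2.16 ± 0.44 and Egr1 by 2.98 ± 0.95 (adjusted p = 0.0155, and 0.189 with voom). Egr1 was at −2.37 without the library labelled ERK2 KO 2 and at −2.28 without ERK2 KO 3. Of 22 MAPK components, 6 rose and 4 fell (6 and 4 adjusted over the list alone; median 0.024), with the growth factor receptor Egfr lower by 2.43 ± 0.59 (−3.57 without the library labelled double KO 7). Of 14 bile acid synthesis genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; median −0.012), with Cyp7a1 higher and Cyp7b1, of the alternative pathway, lower by 2.18 ± 0.57 (adjusted p = 0.00495), or by 3.31 without the library labelled double KO 7.

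Of 21 fatty acid and triglyceride synthesis genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone; median 0.12), with Scd2 higher by 1.80 ± 0.28. Of 31 fatty acid oxidation and PPAR-alpha targets, 7 rose and 11 fell (7 and 11 adjusted over the list alone; median −0.30), with the hormone Fgf21 higher by 3.48 ± 0.97 and Vnn1 lower by 3.44 ± 0.96 (−5.80 without the library labelled double KO 7). Of 24 cholesterol genes, 3 rose and 2 fell (1 and 1 adjusted over the list alone, median 0.22), but 9 rose and 1 fell when scaled by library size alone. Of 14 lipoprotein genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone, median −0.14), with Apoa4 higher by 2.19 ± 0.50. Of 20 glucose and glycogen genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone; median −0.31), with Irs2 lower by 1.47 ± 0.35. Of 21 pericentral genes, 5 rose and 7 fell (5 and 7 adjusted over the list alone; median −0.089), with Cyp2e1 lower by 1.61 ± 0.31, and of 16 periportal genes, 3 rose and 7 fell (4 and 7 adjusted over the list alone; median −0.40), with Cdh1 lower by 2.05 ± 0.52 (−3.09 without the library labelled double KO 7). Of 19 xenobiotic metabolism genes, 8 rose and 8 fell (8 and 8 adjusted over the list alone; median −0.26). Medians of the bile acid synthesis, lipoprotein and pericentral lists changed sign with another scaling.

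Of 15 p53 targets, 4 rose and 2 fell against the ERK2 knockout (4 and 2 adjusted over the list alone; median 0.16), with the cell cycle inhibitor Cdkn1a higher by 2.80 ± 0.66 and Gdf15 lower by 3.46 ± 0.65. Of 23 autophagy and lysosome genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone, median 0.13), but 11 rose and 1 fell when scaled by library size alone. Of 26 acute phase genes, 7 rose and 10 fell (9 and 10 adjusted over the list alone; median 0.036), with the orosomucoid Orm3 higher by 3.69 ± 0.80. Of 23 interferon genes, 0 rose and 3 fell (0 and 0 adjusted over the list alone; median 0.045), with the GTPase Iigp1 lower by 2.05 ± 0.63 (−2.66 without the library labelled double KO 7). Of 19 clock genes, 3 rose and 4 fell (2 and 3 adjusted over the list alone; median 0.013), with Ciart higher by 4.36 ± 1.16. Of 20 female-biased genes, 7 rose and 10 fell (7 and 10 adjusted over the list alone; median −0.71), and of 7 fetal liver genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone; median −0.69). Of 9 cholangiocyte markers, 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.86), with Spp1 higher by 2.84 ± 0.49 and Epcam by 1.59, and the list was called upward in the matching libraries (adjusted p = 0.0417 and adjusted p = 0.467 with an estimated correlation). In this comparison 2 of 13 lymphocyte markers rose (2 adjusted over the list alone; median 0.60), and 0 of 2 erythroid markers did (median 0.78). Median, mean and test differed in sign for the ERK target, MAPK, bile acid synthesis, fatty acid synthesis, lipoprotein, acute phase, interferon, clock and fetal lists.

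Genes that set the double knockout apart from both single knockouts were taken where the double knockout differed in the same direction from each. The 8 largest rises were those of Gpx2, Gstm3, Sult2a1, Sult2a5, Gpnmb, Chil3, Amn and F13a1. Sult3a1, Cyp3a44, Cyp3a41a, Cyp2b9, Cyp2b13, Cyp2a4, Rgs16 and Oxtr were the 8 largest falls. In all 1374 genes were higher and 1262 lower than in both single knockouts (2636), and 2498 and 2470 (4968) in the matching libraries. Scaled by library size alone, 2390 were higher and 763 lower. The count was 3980 without the library labelled ERK1 KO 1, 1663 without ERK1 KO 3, 1654 without ERK1 KO 4, 1670 without ERK1 KO 5, 1460 without double KO 4, 1540 without double KO 6 and 4904 without double KO 7.

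Both comparisons use the same double knockout libraries, so calls shared between them were set beside what sharing gives. Genes called in each separately with the same sign numbered 1573 higher and 1484 lower, with 0 in opposite directions. Independent lists of these sizes would share 420 and 340. In 20 simulated data sets with no difference 0 were shared, but calls there were too few for sharing to be counted. Across genes, which are not independent replicates, the log2 fold changes of the comparisons correlated at r = 0.907 (0.497 in simulated data) and had a covariance of 0.567 (0.039 simulated). After the double knockout libraries were divided between the comparisons, the calls were too few for sharing to be counted, with 0 shared and 0 given by independent lists. The fold changes then had r = 0.748 and a covariance of 0.522. In the matching libraries, 2669 genes were higher and 2655 lower in both comparisons and 7 went opposite ways, against 854 and 824 for independent lists. There the divided libraries shared 1992 higher and 1796 lower genes, against 545 and 477, with a covariance of 1.01 (1.03 undivided, 0.0345 simulated).

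**Figure D2:**
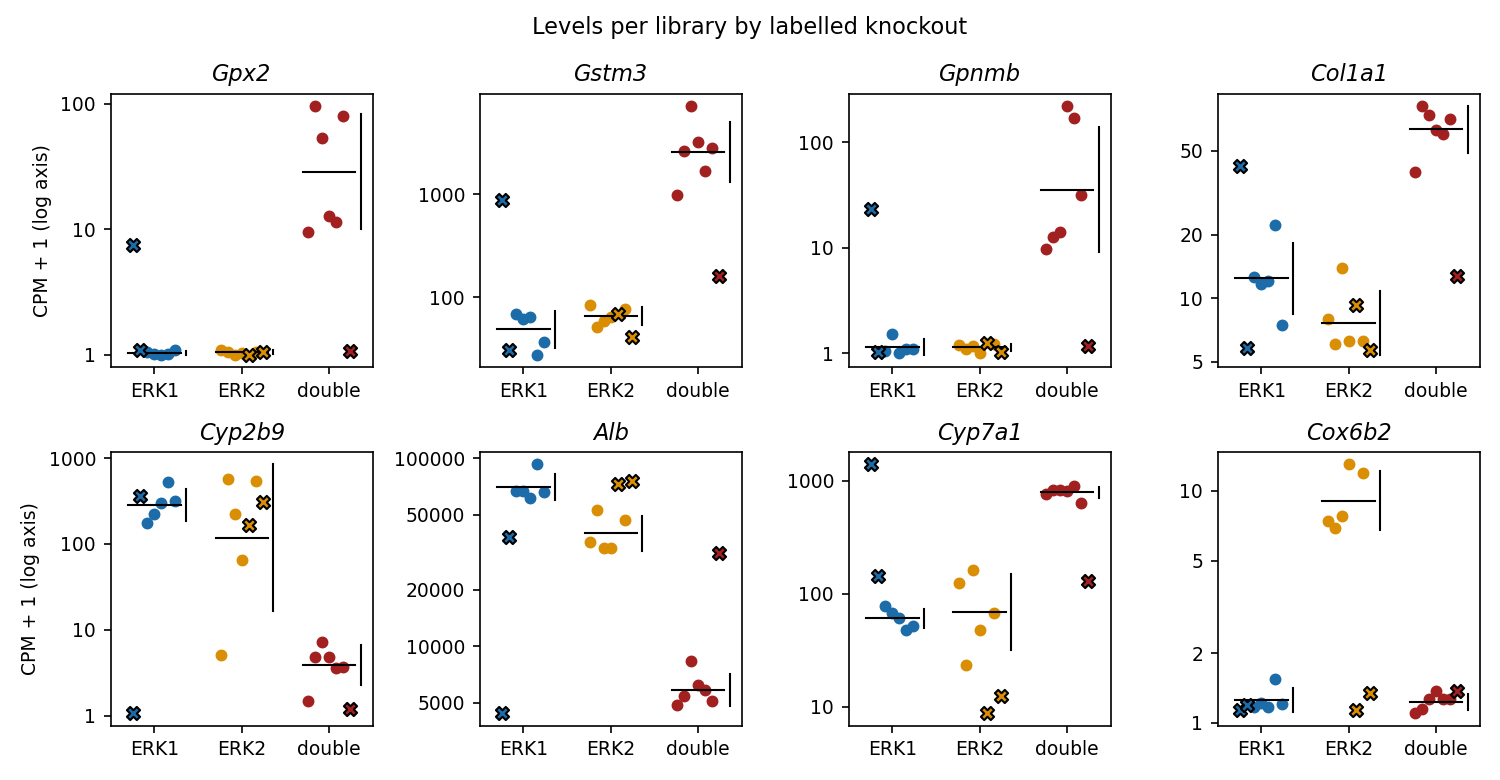
Level of 8 genes in each of the 21 libraries as CPM plus 1 on a log axis, by labelled knockout; points are matching libraries, crosses the 5 libraries at odds with their labels, horizontal lines the geometric mean of the matching libraries and vertical lines 1 SD of their log values on either side. The library labelled double KO 7 lies below every matching double knockout library for Gpx2 (0.0787 CPM), Gstm3 (159 CPM) and Cyp2b9 (0.21 CPM), of which the last is low in the double knockout, and Cox6b2 averages 8.39 CPM in the matching ERK2 knockout libraries against 0.261 CPM in the ERK1 knockout.

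**Figure D3:**
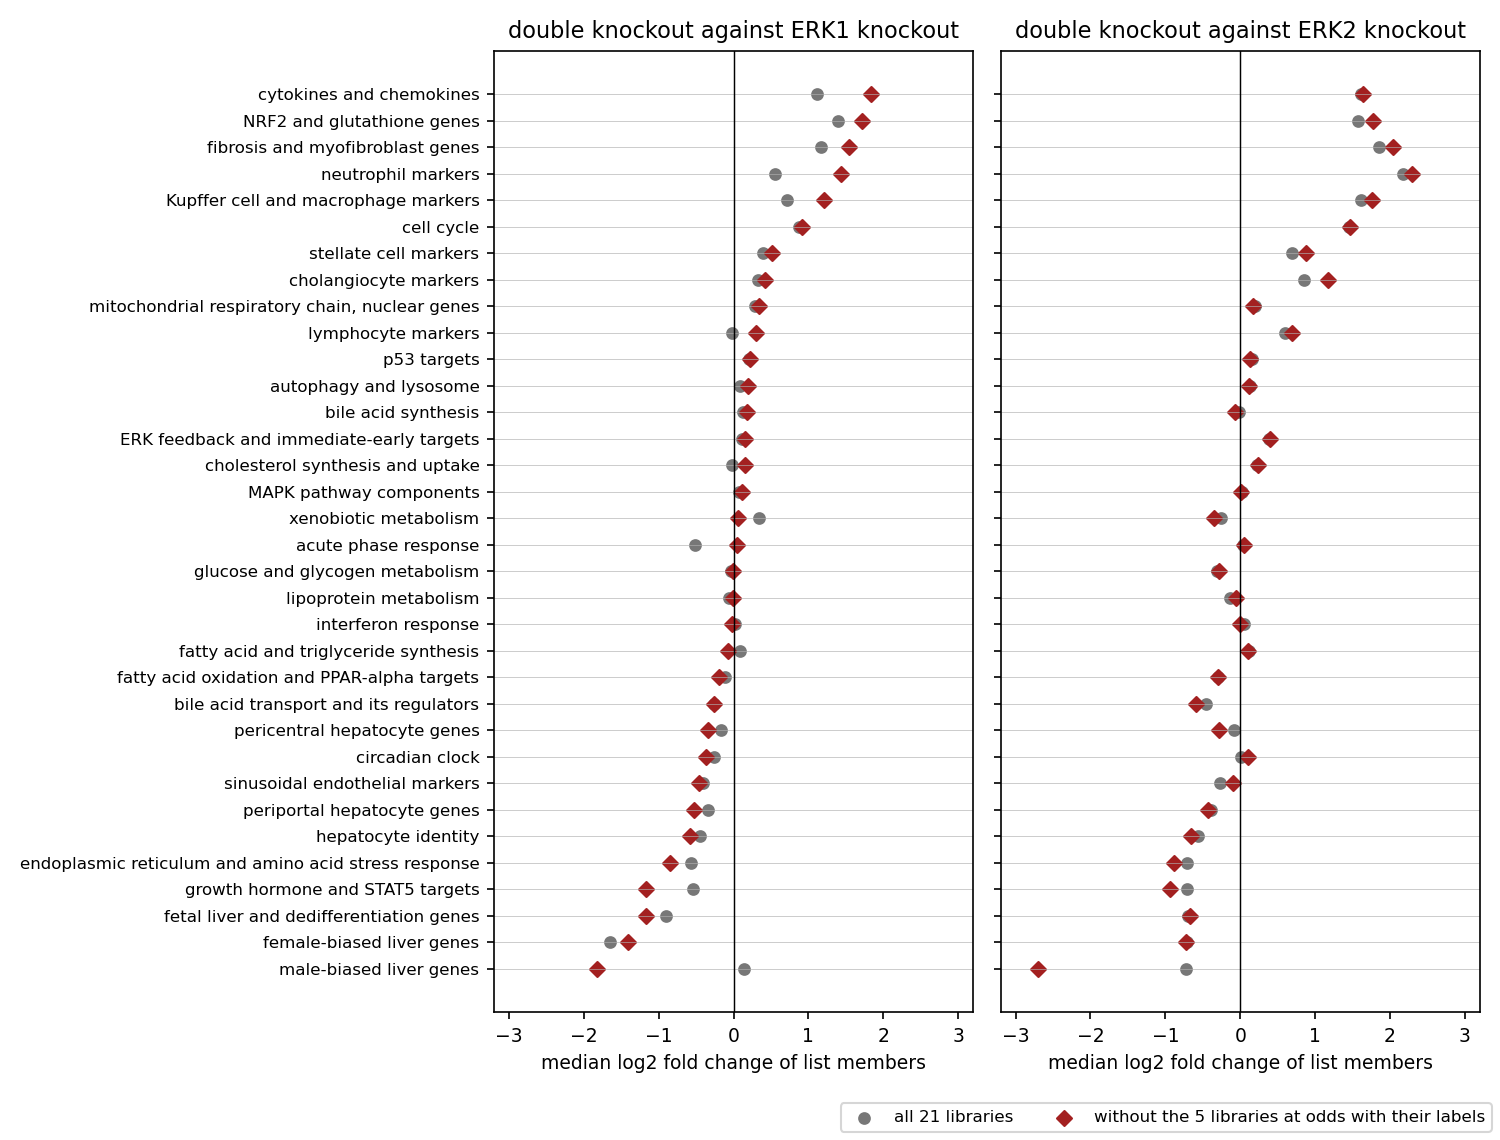
Median log2 fold change of the tested members of gene lists in the double knockout against the ERK1 knockout and against the ERK2 knockout, with grey circles for all 21 libraries and red diamonds for the 16 matching libraries. The median of macrophage markers against the ERK1 knockout is 0.72 with all libraries and 1.21 in the matching ones.

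The ERK2 knockout was set against the ERK1 knockout to ask how the loss of the kinases singly differs. Cox6b2, an isoform of a cytochrome oxidase subunit otherwise typical of testis (chromosome 7, 4751792 to 4753094), was higher in the ERK2 knockout, at 6.06 ± 4.59 against 0.233 ± 0.136 CPM, a log2 fold change of 4.75 ± 0.70 (n = 7 each, adjusted p = 0.0155). It was the 1 gene called by edgeR among 14154, with 1385 at an unadjusted p under 0.05, 22 called by DESeq2 and 1 by voom. In the matching libraries 44 genes were higher and 59 lower (103 in all), and Cox6b2 was higher by 5.07 (adjusted p = 1.52e-06). The call of Cox6b2 was lost with voom (adjusted p = 0.191), with only the compared groups fitted (0.233), and without the library labelled ERK1 KO 2 (0.0706), ERK1 KO 3 (0.0702), ERK1 KO 4 (0.0683), ERK1 KO 5 (0.0716) or ERK1 KO 7 (0.0735). Without these 5 in turn 0 genes were called, and 2 were called without ERK1 KO 1. Presence of Cre is part of this contrast, and so is any other difference between mice with and without the Erk1-null allele.

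No list member passed the test over all genes between the single knockouts. Adjusted over the list alone, 1 glucose gene rose, and 5 female-biased and 4 neutrophil genes fell. The smallest adjusted p of a member was that of Sult2a1 (−6.53 ± 1.47, adjusted p = 0.398, and 0.00654 with DESeq2). The glucose-6-phosphatase gene G6pc was at 0.82 ± 0.20 (adjusted p = 0.497, and 0.0261 with DESeq2). The macrophage gene Gpnmb was at −4.43 ± 1.66 (adjusted p = 0.497), or −0.12 in the matching libraries and 0.11 without the library labelled ERK1 KO 1. Median, mean and test of a list differed in sign for the ERK target, bile acid synthesis, fatty acid synthesis, fatty acid oxidation, lipoprotein, pericentral, xenobiotic, NRF2, stress response and interferon lists.

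Between the single knockouts camera called 14 of the 34 lists, 4 higher and 10 lower in the ERK2 knockout, and 18 in the matching libraries. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05 (3 in the matching libraries), and fry called 0 (3 in the matching libraries). Higher in the ERK2 knockout were male-biased genes (median 0.86, adjusted p = 1.86e-06 and adjusted p = 0.46 with an estimated correlation), the respiratory chain (0.083, 2.53e-05; 0.52), bile acid transport (0.13, 0.00642; 0.46) and xenobiotic metabolism (0.093, 0.033; 0.46). Lower were markers of macrophages (median −0.84, adjusted p = 6.01e-06 and adjusted p = 0.489 with an estimated correlation), neutrophils (−1.37, 0.000368; 0.46), lymphocytes (−0.53, 0.000848; 0.489), stellate cells (−0.31, 0.0109; 0.529), cholangiocytes (−0.46, 0.0293; 0.46) and sinusoidal endothelium (−0.13, 0.0296; 0.607). Fibrosis genes (−0.68, 9.78e-05; 0.489), female-biased genes (−1.20, 0.000368; 0.462), cytokines (−0.62, 0.0211; 0.607) and cell cycle genes (−0.56, 0.0265; 0.607) were also lower. Several of these medians moved in the matching libraries: to −0.51 for macrophage markers, −0.93 for neutrophil markers, −0.45 for fibrosis genes and −0.30 for cytokines. Cytokines were no longer called there (adjusted p = 0.219). The medians were 0.16 for the respiratory chain, 0.21 for bile acid transport and 0.20 for xenobiotic metabolism in the same libraries. With all 21 libraries scaled by library size alone, they were 0.0076, 0.068 and 0.018 in this order. That scaling put the median of all genes at −0.083. Medians of the MAPK, fatty acid oxidation, glucose and p53 lists changed sign under another scaling of the libraries. The other 20 tested lists were not called, with medians between −0.46 and 0.12.

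The Mapk3 locus was checked for a cluster of changed neighbours. Within 10 Mb of Mapk3, 38 of 178 tested genes were called in the double against the ERK1 knockout (21.3%, against 24.3% elsewhere). Against the ERK2 knockout, 83 of 178 genes near Mapk3 (46.6% against 44.7%) were called, and between the single knockouts 0. The adjusted p of Fisher's exact test was 0.974, 0.974 and 1 in this order, and 1 in each comparison at distances of 5 and 20 Mb.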

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

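The tests of the 5 libraries and of the share of hepatocytes were chosen only after the result was seen; the splits of the samples and the test of scaling were set earlier.

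Single libraries stood far from the other 6 of their group in 24 of 75 group values tested. For normally spread values, chance alone gives about 1 in 20, or 3.75. Of the 24, 19 were in the 5 libraries at odds with their labels. Each value is the gap to the nearest library divided by the range of the group. The library labelled ERK1 KO 1 stood high for Gpx2 (0.955), Mmp12 (0.867), Gpnmb (0.865), Amn (0.8), H2-Q1 (0.765), Gstm3 (0.734) and F13a1 (0.587), low for Cyp2b9 (0.819) and Meg3 (0.668), and apart on the main axis of variation (0.66). The library labelled double KO 7 stood low for Sult2a1 (0.928), H2-Q1 (0.868), Sult2a2 (0.813), Sult2a5 (0.659) and Mmp12 (0.612), high for Mapk3 (0.79), and apart on the main axis (0.697), while its Cyp2b9, at 0.21 CPM, was as low as in the other double knockout libraries. The library labelled ERK1 KO 2 stood high for Mapk3 (0.665), and the library labelled ERK2 KO 5 stood apart in total counts (0.618). Among the matching libraries, double KO 2 stood apart for Sult3a1 (0.796), Cyp3a41a (0.746) and Oxtr (0.685). ERK1 KO 6 did so for Cox6b2 (0.768) and ERK2 KO 2 for Sult2a5 (0.751). As log2 of CPM plus 1, these levels were 0.498, 0.27, 0.907, 0.618 and 0.573 in this order. All lie near the floor, so these ratios compare low levels.

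The first pattern is the 5 libraries themselves: incomplete action of Cre is argued against, since Cre does not act on Mapk3 and Mapk3 went against the label in 4 of the 5, and mixed RNA of different genotypes is argued against for these 4 by 0 of their Mapk3 values lying between the ranges of the other 16, a test that does not bear on the library labelled ERK1 KO 1. Wrong genotype labels remain a candidate explanation: with the targets left out, 5 of the 5 lay nearest to another group over the 100 top genes of each comparison, while 16 of the 16 others lay nearest to their own. The library labelled ERK1 KO 1 lay nearest to the double knockout, those labelled ERK2 KO 5 and ERK2 KO 7 to the ERK1 knockout, and those labelled ERK1 KO 2 and double KO 7 to the ERK2 knockout, for ERK1 KO 2 by little (mean squared log2 distance 0.493 against 0.66 to the ERK1 knockout). Against an origin of these last 2 in the ERK2 knockout, Cox6b2 was at 0.188 CPM in ERK1 KO 2 and 0.367 CPM in double KO 7. The matching ERK2 knockout libraries were at 5.9 to 12 CPM. Cyp2b9 was at 0.21 CPM in double KO 7 against 4.08 to 564 CPM in those libraries. Of 101 genes called between the single knockouts in the matching libraries, targets left out, 64 in ERK1 KO 2 and 76 in double KO 7 lay nearer to the ERK2 knockout. In ERK2 KO 5 and ERK2 KO 7, 93 and 83 lay nearer to the ERK1 knockout. Gdpd3, the gene next to Mapk3, went the other way, at 0.589 CPM in ERK1 KO 2 and 0.157 CPM in double KO 7. It was at 0.225 to 0.796 CPM in the matching ERK2 knockout libraries and at 9.69 to 43.5 CPM in the other matching libraries. In ERK2 KO 5 and ERK2 KO 7 it was at 9.96 and 13.8 CPM. Mapk3 was at 39.9 CPM in ERK1 KO 2 and 36.5 CPM in double KO 7. The matching Erk1-null libraries were at 5.18 to 12.2 CPM, which argues against an Erk1-null genotype for both. Cox6b2 in both, and Cyp2b9 in double KO 7, were unlike the matching ERK2 knockout libraries. Which group ERK1 KO 2 and double KO 7 came from therefore stays open. ERK1 KO 1 lay clearly nearer to the double knockout (distance 0.371, against 4.13 to the ERK1 knockout). ERK2 KO 5 and ERK2 KO 7 lay clearly nearer to the ERK1 knockout (0.13 and 0.169, against 0.845 and 0.723 to the ERK2 knockout). These distances do not establish how the labels arose. No library was moved to another group, and no record of the samples was examined.

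The second pattern is the fall of hepatocyte genes with the rise of macrophage and matrix genes in the double knockout. A lower share of hepatocytes alone would raise the markers of every other cell type alike. In the matching libraries the median of macrophage markers exceeded that of sinusoidal endothelial markers by 1.67 against the ERK1 knockout (1.21 against −0.46, two-sided permutation p = 3e-05 over 100000 resamples of the members). Against the ERK2 knockout it did so by 1.85 (1.76 against −0.093, permutation p = 2e-05). Members of a list may vary together, so these p-values do not measure the spread between libraries. The gap argues against a lower share of hepatocytes as the only cause. It does not exclude such a fall beside other changes. The weakest of the hepatocyte and macrophage medians stayed at −0.45 under total-count scaling in the matching libraries and at −0.35 with all 21. The medians thus kept their sign under either scaling. Total counts are themselves open to distortion by a few abundant genes, so this test cannot by itself exclude such distortion. A lower share of hepatocytes beside other changes, more macrophages, more matrix-producing cells, or higher expression of these genes in cells already present may each contribute and were not separated. The knockout itself stays among the open explanations.

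Other splits of the same libraries bear on each count of changed genes, and 100 were counted for each. For the double against the ERK1 knockout, 2 of 100 splits, the real one included, called at least as many genes as the real one (3402). So high a count was uncommon among these splits, but the highest other split called 7110, more than the real one. It exchanges the libraries labelled ERK1 KO 1 and double KO 7, which points to a structure of the samples. For the double against the ERK2 knockout, 1 of 100 called as many (6312 in the real split, 6302 in the highest other, which moves the libraries labelled double KO 7 and ERK2 KO 6). For the double against both it was also 1 of 100 (2636, highest other 0). A share of 1 in 100 is the lowest that 100 splits can give. Splits for the double against both assigned all 21 libraries anew, so they bear only on whether any group differs. For the ERK2 against the ERK1 knockout 2 of 100 called at least the 1 gene of the real split, the highest other calling 1 after moving the libraries labelled ERK1 KO 5, ERK1 KO 6, ERK2 KO 5 and ERK2 KO 7. A count of 1, set against counts of mostly 0 and lost without any 1 of 5 ERK1 knockout libraries, is too small for this share to exclude chance.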

How the results depend on the processing

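Fits without the 5 libraries were chosen only after the result was seen. The double against the ERK1 knockout gave 6953 genes with voom, 1520 with only the compared groups fitted, 945 at an absolute log2 fold change over 1, 6551 without the 5 libraries and 2094 to 5609 without 1 library. Against the ERK2 knockout the count was 2203 at an absolute log2 fold change over 1 and 5398 to 7522 without 1 library. Against both it was 5747 with voom, 807 at an absolute log2 fold change over 1, 4968 without the 5 libraries and 1460 to 4904 without 1 library. The ERK2 against the ERK1 knockout gave 0 genes with at least 1 CPM required in 7 libraries, 22 with DESeq2, 0 with only the compared groups fitted, 103 without the 5 libraries and 0 to 2 without 1 library. Lists called were 0 in each of the 3 comparisons with an estimated correlation, with all libraries and without the 5, and 10 to 13, 13 to 15 and 10 to 15 without 1 library.

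Without the 5 libraries Mapk3 was at −0.68 (double against ERK1 knockout) and 1.91 (ERK2 against ERK1 knockout), each then past the threshold. The 5 had been set apart in part by their Mapk3 level, so these calls are not independent of that choice. Without 1 library Mapk3 ran from −1.17 to 0.20 (double against ERK1 knockout) and from −2.27 to −1.35 (against ERK2 knockout). Between the single knockouts Gpnmb ran from −4.65 to 0.11, reversed without the library labelled ERK1 KO 1, and Slc4a1 from −0.25 to 0.92, reversed without ERK2 KO 6; neither was called. Of the values of named genes under the alternatives, 6723 kept their direction and side of the threshold. Of the others, 393 lost the call, 8 gained it and 2 reversed. The cause of these changes was not tested, beyond fewer libraries in some fits. The 6723 include genes not called in the main fit. They also include fold changes that moved in size, such as that of Gpnmb against the ERK1 knockout, by 23.4 times without ERK1 KO 1. No paired analysis was possible because the labels give each sample its own number and none is shared between groups.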

Other observations

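The tests of gene position were chosen only after the result was seen, as were the genes named.

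Without the 5 libraries, 10 genes other than Mapk3 differed between the single knockouts by more than 4-fold and passed the test. Gdpd3, a lysophospholipase D gene next to Mapk3 (chromosome 7, 126766414 to 126775645), was at 20.7 ± 7.12 CPM in the ERK1 knockout (n = 5), 0.446 ± 0.211 CPM in the ERK2 knockout (n = 5) and 22.1 ± 11.1 CPM in the double knockout (n = 6), a log2 difference of −5.46 between the single knockouts (adjusted p = 1.59e-06). Its counts in libraries with the Erk1-null allele were not separated from read-through of the targeted Mapk3 allele, so they are not shown to be Gdpd3 transcripts. Gm3435 had 0 counts in all 5 ERK2 knockout libraries and was at 0.744 ± 0.171 CPM in the ERK1 knockout, at least 9.65-fold higher against a floor of 3 counts in a library. Srp54a (−4.31, adjusted p = 1.59e-06), Hddc3 (−2.59) and Erdr1 (−2.23) were also lower in the ERK2 knockout. Cox6b2 (5.07, adjusted p = 1.52e-06), the carboxylesterase Ces4a (5.47, adjusted p = 0.029, at 88.0 ± 90.8 against 2.12 ± 1.01 CPM), Serpina3c (4.71), Trim72 (2.98) and the nucleoside transporter Slc28a1 (2.48) were higher. The double and the ERK1 knockout both carry the Erk1-null allele. Between them Ces4a (−4.48, adjusted p = 0.0125) and Slc28a1 (3.24, adjusted p = 6.29e-05) differed by the test. The other 8 did not pass it, which does not show that they were equal. For 9 of the 10 genes the double knockout differed from the ERK2 knockout by the test, in the same direction as the ERK1 knockout did.

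Variants carried on the Erk1-null line elsewhere on chromosome 7 are a candidate explanation that stays open: of the 10 genes 5 lie on chromosome 7, which holds 7.77% of the tested genes and Mapk3 (odds ratio 11.9, 95% interval 2.74 to 51.9, two-sided Fisher's exact p = 0.000509). The 5 include Gdpd3, with the limit given above, and Slc28a1, which differed between the double and the ERK1 knockout although both carry that line's allele, so neither counts for it. Among genes not called between these groups, Gdpd3 left out, 3 of 7 lay on chromosome 7 (Cox6b2, Hddc3 and Trim72; odds ratio 8.98, 95% interval 1.31 to 53.2, Fisher's exact p = 0.0127), and beyond 10 Mb of Mapk3 it was 2 of 6 (7.23, 0.652 to 50.6, p = 0.053), too few to decide. Whether called genes gather within 10 Mb of Mapk3 itself also stays open: 2 of 97 did, an odds ratio of 1.61 with a 95% interval of 0.19 to 6.05 (two-sided Fisher's exact p = 0.36). Loss of ERK1 itself remains among the open explanations and was not tested, and no sequence of the strains was analysed here.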
